A study of Homo sapiens and Mus musculus with 14 samples.

How the data were processed

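The values analysed are the deposited tables of normalised read counts, 1 for each cell line. The submitters list alignment with HISAT2, counting with featureCounts and normalisation with DESeq2, with the builds mm10 for MIN6 and hg19 for EndoC-bH3, and give no versions. MIN6 RNA was extracted with Trizol and prepared with the Illumina TruSeq stranded mRNA kit, and EndoC-bH3 RNA with the Quick-RNA Microprep and ABclonal mRNA-seq kits. Per the file headers, the deposited signal comes from alignments with duplicates removed. Each column behaved as read counts divided by 1 factor per library, and multiplying by that factor gave whole reads for 100% of the positive values, within 0.001 of a whole number. Those recovered reads give the depths in the report and are the input of edgeR and DESeq2.

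The main test was limma (3.58.1) with a trended prior on log2(value + 1), over genes with a value of at least 10 in at least 3 libraries, or in at least 2 where the siRNAs were fitted separately. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are knockdown minus control, or siRNA 1 minus siRNA 2. Each comparison was repeated with batch as a block, and with edgeR (4.0.16) quasi-likelihood and DESeq2 (1.42.0) on the recovered reads. In the pooled fit siRNA 2 is absent from batch 3. Single genes of interest were also tested with exact permutation tests of all arrangements of the libraries. The versions used were R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The comparisons, gene lists and naming rule were fixed before the data were examined.

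The 20 gene lists (591 members, 590 entries found in each line) were tested with camera at a preset correlation between genes of 0.01, with a correlation estimated from the data, and with fry. A list was tested with at least 5 members. "Adjusted over the list alone" means that the correction covered the members of that list.

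The report names the target and insulin genes, 13 ER stress and β-cell genes fixed in advance, and up to 12 genes in each direction by size of the log2 difference, among called genes with a mean of at least 50 that moved the same way in each knockdown library against the control of its batch. Where there was no such gene, the 10 with the smallest p under the same condition are named. Up to 4 members with the smallest p stand for each list that passed, and up to 5 genes in each direction for siRNA 1 against siRNA 2. The MIN6 table holds 26 symbols altered to date-like strings, which are not named. Some genes that the naming rule covers are not reported here.

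Batch numbers pair the EndoC-bH3 libraries. The correlation across genes of their deviations from the group means was 0.809 to 0.939 for the 7 pairs of libraries with the same number and −0.939 to 0.821 for the 14 pairs with different numbers. In MIN6 these ranges were −0.0748 to 0.259 (3 pairs) and −0.263 to 0.17 (6 pairs). The blocked values are therefore printed beside the others where they change a call, or a count by over 1.5 times. In a chi-square comparison of recovered reads, shNT libraries 1 and 2 were the closest pair, with 1.87 per gene over 13638 genes with at least 20 reads, against 11.9 and 15.9 for the other shNT pairs, and 1.18 over genes under 1000 reads. The comparison is with counting noise alone and does not show that they are separate replicates. They were kept as separate libraries, and limma also called 0 genes with their mean as 1 replicate. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries.

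The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For MIN6, limma recovered 14% and 75% of them and called 0 unchanged genes, with the block 37% and 86% with 5 unchanged genes called, edgeR 14% and 75% with 1, and DESeq2 44% and 86% with 2. The simulated libraries kept batch effects shared by the same batch number, so a gain from the block was built in. The MIN6 libraries showed little such pairing (correlation −0.0748 to 0.259). There the block lowered the genes at a limma unadjusted p under 0.05 from 1279 to 1003. The simulated MIN6 shares may therefore not hold for these libraries. For the pooled EndoC-bH3 comparison, limma recovered 27% and 68% with 0 unchanged genes called, with the block 71% and 93% with 9, and DESeq2 51% and 86% with 3.

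Mouse positions are from GENCODE M21 (mm10). No human positions are given, since the deposited build differs from that of the annotation used (GENCODE 44). Transcripts for the 7-base searches came from the same annotations. Mouse and human genes were matched by symbol in capitals, not by an orthology table.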

Results

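Messenger RNA was sequenced from a mouse and a human insulin-producing cell line after depletion of PDIA6, a protein disulfide isomerase of the endoplasmic reticulum (ER). MIN6 is a mouse insulinoma line, and EndoC-bH3 is a conditionally immortalised human pancreatic β-cell line. MIN6 cells carried a non-targeting short hairpin RNA (shNT, 3 libraries) or a hairpin against Pdia6 (shPdia6, 3 libraries). Each of the 3 batches used a different Pdia6 hairpin, so hairpin and batch cannot be separated in MIN6. EndoC-bH3 cells received a non-targeting siRNA (siNT, 3 libraries from batches 1 to 3), siRNA 1 against PDIA6 (3 libraries from batches 1 to 3) or siRNA 2 (2 libraries from batches 1 and 2). The series concerns regulators of proinsulin, and the comparisons ask which transcripts differ once PDIA6 is depleted. The MIN6 table listed 25230 genes. Its shNT libraries held 18559735, 15063603 and 9116880 reads and its shPdia6 libraries 24755916, 1987770 and 22556147, in batch order. The EndoC-bH3 table listed 28265 genes. The siNT libraries held 35643959, 31344615 and 20935227 reads, the siRNA 1 libraries 37369357, 30238482 and 25235941, and the siRNA 2 libraries 36878430 and 22882244. In a principal component analysis of the EndoC-bH3 libraries, the first component (71.2% of the variance) set batch 1 apart from the other batches, the second (15.1%) set siRNA 1 apart and the third (6.38%) set siRNA 2 apart. The first component of the MIN6 libraries (56% of the variance) set apart the shPdia6 library of batch 2, which was also the shallowest, and the second (27.6%) the shPdia6 library of batch 1.

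The targeted transcript was lower in every knockdown library of both lines. In MIN6, Pdia6 (ENSMUSG00000020571.12, mm10 chromosome 12, 17266545 to 17284770, plus strand) had a normalised read count of 26310 ± 750 (SD, n = 3) with shNT and 5069 ± 3050 (SD, n = 3) with shPdia6, which is 19.3% of the control level. Relative to the shNT library of the same batch, Pdia6 stood at 8.44%, 18.4% and 30.4% in batches 1, 2 and 3. The log2 difference was −2.58 ± 0.44 (SE), with a limma adjusted p of 0.274, or 0.643 with batch as a block, and DESeq2 called it (adjusted p = 3.11e-07). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. In EndoC-bH3, PDIA6 fell from 3142 ± 224 (SD, n = 3) to 197 ± 43.2 (SD, n = 5), or 6.27% of control. The log2 difference was −4.01 ± 0.20 (SE), the limma adjusted p was 0.000286, and the exact two-sided permutation test gave p = 0.0179, the smallest of its 56 arrangements. Within batches the log2 difference lay between −4.44 and −3.54. Both siRNAs lowered PDIA6 to a similar level, 195.1 ± 37.2 (SD, n = 3) with siRNA 1 and 199.8 ± 68.2 (SD, n = 2) with siRNA 2. Their difference was −0.08 ± 0.18 (log2, SE) with batch as a block (adjusted p = 0.798).

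Insulin transcripts, the messages for proinsulin, did not pass the test in either line. In MIN6, Ins1 (mm10 chromosome 19, 52264297 to 52265476, plus strand) stood at 6410 ± 649 (SD, n = 3) with shNT and 8154 ± 5990 (SD, n = 3) with shPdia6. Ins2 (chromosome 7, 142678656 to 142743381, minus strand) stood at 54720 ± 5160 and 64190 ± 46700 (SD, n = 3 each). These genes are close paralogs, and reads that fit both may have been assigned to either. The wide spread came from the shPdia6 library of batch 2, where Ins1 reached 241% and Ins2 223% of the shNT library of that batch. In the shPdia6 libraries of batches 1 and 3, Ins1 lay at 69.5% and 75.1% and Ins2 at 67.6% and 66.7%. Those libraries were the deepest in MIN6, and their 100 most abundant genes had medians of −0.189 and −0.186 (log2). Both medians are relative to shNT of batches 1 and 2, so the lower insulin values there cannot be told apart from depth. Without the batch 2 library the log2 differences were −0.45 for Ins1 and −0.55 for Ins2, against 0.11 and 0.0015 with all libraries. The exact two-sided permutation test gave p = 1 for each. Without shNT of batch 1 or 2, Ins2 differed by −0.05 and −0.02. In EndoC-bH3, INS stood at 28730 ± 9310 (SD, n = 3) with siNT and 25170 ± 8870 (SD, n = 5) with the PDIA6 siRNAs, a log2 difference of −0.21 ± 0.33 (SE), with an exact two-sided permutation p of 0.518. INS was below the siNT library of its batch in 4 of 5 libraries, by −0.40 to 0.34 (log2) across them. Without siNT of batch 3 the difference was 0.013. Once batch was a block, INS differed by −0.15 ± 0.13 (log2, SE; limma adjusted p = 0.558) with the siRNAs pooled, −0.26 ± 0.10 (0.0737) with siRNA 1 and 0.05 ± 0.12 (0.823) with siRNA 2, and by −0.31 ± 0.12 (0.0823) between the siRNAs.

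**Figure D1:**
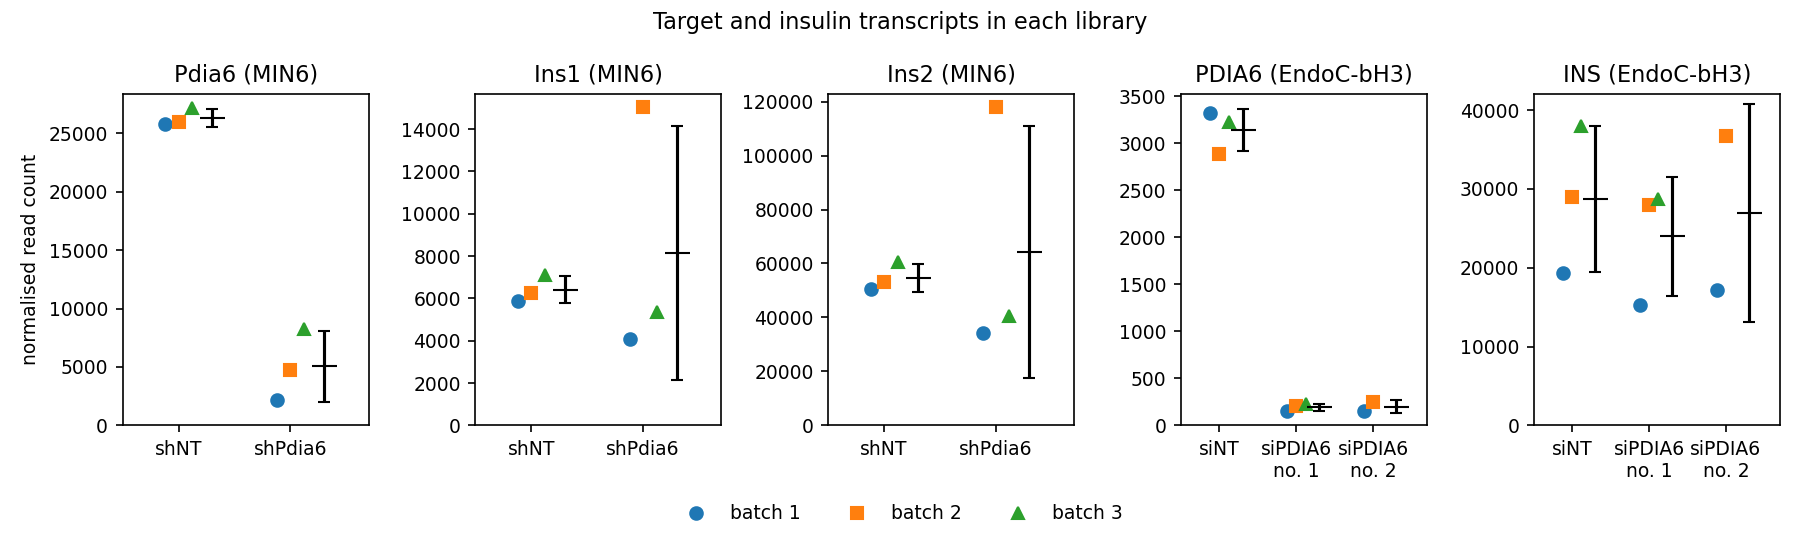
Normalised read counts per library of the targeted gene and the insulin genes in MIN6 (Pdia6, Ins1, Ins2) and EndoC-bH3 (PDIA6, INS), on linear axes from 0. Points are libraries, coloured by batch, and bars give the mean with its SD; PDIA6 is at 6.27% and Pdia6 at 19.3% of control, while the shPdia6 library of batch 2 reaches 118000 for Ins2.

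In MIN6, the comparison of 3 shPdia6 with 3 shNT libraries covered 13175 genes, and limma called 0 of them. At an unadjusted p under 0.05 there were 1279 genes. The edgeR quasi-likelihood test also called 0, and DESeq2 called 91 (55 higher and 36 lower). The genes named here have the smallest p among those that moved one way in each batch, and each missed the threshold with limma and edgeR, while DESeq2 called all 10. Actr2, a subunit of the actin-nucleating Arp2/3 complex, was at 1195 ± 72.3 with shNT and 2557 ± 150 with shPdia6 (SD, n = 3 each; log2 difference 1.10, limma adjusted p = 0.169). The other 9 genes had an adjusted p of 0.274. Cth, which encodes the transsulfuration enzyme cystathionine γ-lyase, differed by 1.48 (log2), and Trib3, a pseudokinase gene induced by ATF4, by 1.20. Nr1d1, which encodes the circadian repressor REV-ERBα, differed by 1.48, and Rnf149, a ubiquitin ligase gene, by 1.26. Frzb, a secreted Wnt antagonist gene, was the only lower one, at 21.7% of control (log2 difference −2.21 ± 0.28, SE). Pgm2, a phosphoglucomutase gene, Ilrun, Rabl6 and Atxn7l3b differed by 0.75, 0.83, 0.75 and 0.68. The prohormone convertase gene Pcsk1 was at 74.2% and the zinc transporter gene Slc30a8 at 80.4% of control, each lower in 3 of 3 batches. Their limma adjusted p was 0.409 and 0.562. The convertase gene Pcsk2 was at 101% of control and lower in 2 of 3 batches. The chaperone genes Hspa5 and Hsp90b1 differed by −0.0019 and −0.015 (log2), and their signs turned with the tool used.

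Of the 20 gene lists fixed before the data were examined, 6 passed the test in MIN6 with a preset correlation between genes. The PERK-ATF4 and amino acid response list, genes of the integrated stress response, was higher (camera adjusted p = 4.08e-08; adjusted p = 0.357 with an estimated correlation). Of its 37 members 33 had positive values and 4 negative ones, with a median log2 difference of 0.26. Cth and Trib3 passed when adjusted over the list alone, and Eif4ebp1 (0.61) and Chac1 (0.57) did not. The XBP1, translocon and ER export list was lower (adjusted p = 0.00242; adjusted p = 0.76 with an estimated correlation), with 33 of 38 members negative, among them the signal peptidase genes Spcs3 (−0.96) and Sec11c (−0.37), Tram1 (−0.37) and Srp19 (−0.33). The ER chaperone list was also lower (adjusted p = 0.0122; adjusted p = 0.76 with an estimated correlation), with 21 of 25 members negative. Its members with the smallest p were Sdf2l1 (−0.66), Fkbp11 (−0.52) and Dnajb9 (−0.32), and Uggt1 went the other way (0.38). Ribosomal protein genes were lower (33 of 47 negative; adjusted p = 0.00272; adjusted p = 0.76 with an estimated correlation), with Rps7 at −0.44, Rpl7 at −0.35, Rps3 at −0.35 and Rps19 at −0.33. Cell cycle genes were higher (33 of 40 positive; adjusted p = 0.00468; adjusted p = 0.76 with an estimated correlation), including Mki67 (0.41), Cenpf (0.42), Mcm2 (0.29) and Kif11 (0.29). Markers of other islet endocrine cells were lower (8 of 9 negative; adjusted p = 0.00272; adjusted p = 0.471 with an estimated correlation), with the δ-cell hormone gene Sst at −2.41, Irx1 at −1.24, Rbp4 at −1.23 and Irx2 at −0.86. Rbp4 alone passed when adjusted over that list alone, and no member of the 6 lists passed over all genes with limma, while DESeq2 called Cth and Trib3. With batch as a block a seventh list passed, p53 targets and apoptosis (16 of 22 negative, adjusted p = 0.0335; adjusted p = 0.735 with an estimated correlation; 0.0625 without the block). The other 13 lists had camera adjusted p between 0.0508 (prohormone processing) and 0.958 (β-cell dedifferentiation, whose test pointed down while its median was 0.137). Without the shPdia6 library of batch 2, the shallowest, 5 lists passed, and the ER chaperone (0.206), XBP1 and translocon (0.0982) and cell cycle (0.202) lists were not among them. Without the shPdia6 library of batch 3, 2 lists passed, PERK-ATF4 (4.43e-05) and other islet endocrine markers (0.0285). Without that of batch 1, the ribosomal protein list did not pass (0.0554).

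In EndoC-bH3, both PDIA6 siRNAs together (5 libraries) were compared with siNT (3 libraries) over 15847 genes, and limma called 14: 10 rose and 4 fell. RSL24D1, a factor of large ribosomal subunit assembly, rose from 600 ± 93.7 (SD, n = 3) to 1708 ± 310 (SD, n = 5), a fold of 2.83 with a limma adjusted p of 0.0314. CBX1, which encodes the heterochromatin protein HP1β, rose by 1.26 ± 0.10 (limma adjusted p = 0.00805), and TMEM209, a nuclear envelope protein gene, by 1.20 ± 0.13 (0.0314). The glycolytic gene PGAM1 rose by 1.15, the sarcoglycan gene SGCE by 1.14, the small GTPase gene RAP1B by 0.93 and GNPNAT1, an enzyme gene of UDP-N-acetylglucosamine synthesis, by 0.91. The non-coding RNA LINC00674 rose by 0.79 and the desmosomal cadherin gene DSC2 by 0.72. GLIPR2 fell by 1.26 on the log2 scale, the axon guidance receptor gene ROBO1 by 1.02 and CBWD2 by 0.93, and the remaining call was PDIA6. Each of these genes moved the same way in 5 of 5 libraries against the siNT library of its batch, and apart from PDIA6 their limma adjusted p lay between 0.00805 and 0.0374. CBWD2 belongs to a family of near-identical genes, and CBX1, PGAM1 and RSL24D1 have processed pseudogenes, so their counts may be shared with those copies. The other gene that rose was DSC3, a neighbour of DSC2 whose mean count was below the minimum for naming and which is named after its values were seen: it lay at 2.89 to 3.12 with siNT and at 20.8 to 36.5 with the siRNAs (limma adjusted p = 0.0291). Leaving out siNT of batch 1, 2 or 3 left 2, 1 and 1 calls, leaving out siRNA 1 of batch 1, 2 or 3 left 2, 1 and 1, and leaving out siRNA 2 of batch 1 or 2 left 4 and 2.

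With batch as a block, 395 genes passed in EndoC-bH3 (212 rose and 183 fell), and all 14 earlier calls were among them. The genes named in this paragraph, apart from MAFA, were chosen after these values were seen. PSAT1, an enzyme gene of serine synthesis, rose by 2.00 ± 0.35 (log2, SE; limma adjusted p = 0.0377), the cytochrome P450 gene CYP2C19 by 1.71, the alcohol dehydrogenase gene ADH6 by 1.67, the protein S gene PROS1 by 1.58 and METTL7B by 1.49. CABP4, a calcium-binding protein gene, fell by 2.44 ± 0.45, MDGA1 by 2.28, LCN10 by 2.21, NTM by 1.74 and BTBD17 by 1.73. The β-cell transcription factor gene MAFA fell from 3983 ± 1840 (SD, n = 3) to 1617 ± 742 (SD, n = 5). Its log2 difference was −1.43 ± 0.17 (SE) with batch as a block (limma adjusted p = 0.0117) and −1.29 ± 0.43 without (0.514), and it was lower in 5 of 5 libraries, by −1.99 to −1.06. DESeq2 without a block called 289 genes and edgeR with the block 437. The blocked count was 7, 2 and 9 without siNT of batch 1, 2 or 3, 214, 153 and 9 without siRNA 1 of batch 1, 2 or 3, and 833 without siRNA 2 of batch 2.

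Of the 20 lists, 3 passed in the pooled EndoC-bH3 comparison. Genes of β-cell identity and glucose sensing fell as a group, with 24 of 28 members negative (camera adjusted p = 0.000895; adjusted p = 0.178 with an estimated correlation; 5.2e-06 with batch as a block). With the block, MAFA and ISL1 (−0.48) passed over all genes, and 5 members passed when adjusted over the list alone. Among other members, G6PC2, a glucose-6-phosphatase gene of β-cells, differed by −1.71 and RFX6 by −0.35. Cholesterol synthesis genes fell as a group, with 20 of 25 negative (adjusted p = 0.00281; adjusted p = 0.922 with an estimated correlation). TM7SF2 (−0.88) passed with the block, while MVD (−0.62) and CYP51A1 (−0.31) did not pass over all genes with limma, with or without the block. DESeq2 without a block called CYP51A1 (adjusted p = 0.00127). Ribosomal protein genes rose as a group, with 42 of 47 positive (adjusted p = 0.00693; adjusted p = 0.922 with an estimated correlation), with RPS16 at 0.48, RPS19 at 0.27 and RPL18 at 0.24. RPS16 passed with the block. Ribosomal protein genes have many processed pseudogenes, which can share reads. The other 17 lists had camera adjusted p between 0.119 and 0.909. The β-cell identity list passed whichever library was left out, with adjusted p of 0.0199 or lower. The cholesterol list did not pass without siNT of batch 1 (0.18) or siRNA 2 of batch 2 (0.0794). With all libraries it also did not pass under array weights, which weight each library by its spread (camera adjusted p = 0.248). The ribosomal protein list did not pass without siNT of batch 1 (0.99), siRNA 1 of batch 2 (0.245) or 3 (0.124), or siRNA 2 of batch 2 (0.234). The number of lists that passed was 6 without siNT of batch 2 or 3 or siRNA 1 of batch 1, 5 without siRNA 2 of batch 1 and 1 without siRNA 2 of batch 2.

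Each siRNA was then set against siNT in a fit of all 8 EndoC-bH3 libraries over 16196 genes. The ER genes HSPA5, HSP90B1 and PDIA4 stood higher with siRNA 2 than with siRNA 1. With batch as a block, HSPA5 (BiP, the main ER chaperone) rose by 1.38 ± 0.17 (log2, SE) with siRNA 2 and differed by 0.26 ± 0.14 with siRNA 1, and the difference between the siRNAs was −1.12 ± 0.17 (limma adjusted p = 0.0021). HSP90B1 (GRP94) rose by 1.47 with siRNA 2 and differed by 0.17 with siRNA 1 (difference −1.30, adjusted p = 0.00299). PDIA4, another disulfide isomerase gene, rose by 2.39 and differed by 0.48 (difference −1.92, adjusted p = 0.00218). The stress-induced DDIT3 (CHOP) rose by 1.04 with siRNA 2 (difference −0.70, adjusted p = 0.0289) and XBP1 by 0.46 (difference −0.53, adjusted p = 0.00273). MAFA fell with each siRNA, by 1.38 ± 0.16 with siRNA 1 (adjusted p = 0.000351) and by 1.51 ± 0.19 with siRNA 2 (0.00188), and SLC30A8 fell by 0.48 (0.00529) and 0.46 (0.0338). ISL1 and G6PC2 also fell with each. The prohormone convertase gene PCSK2 fell by 0.88 with siRNA 1 and differed by −0.25 with siRNA 2 (difference −0.63, adjusted p = 0.00465), and PCSK1 rose by 0.40 with siRNA 1. Without the block, the limma adjusted p of these genes lay between 0.164 and 1 in each comparison. DESeq2 without a block called PDIA4 with siRNA 2 (adjusted p = 0.000455) and between the siRNAs (adjusted p = 0.0113). ERN1, ATF4, PDX1 and NKX6-1 differed by −0.06, −0.27, −0.16 and −0.12 with siRNA 1 and by −0.53, −0.25, −0.31 and 0.04 with siRNA 2. Of these 4, ATF4 with siRNA 1 passed (adjusted p = 0.0168).

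**Figure D2:**
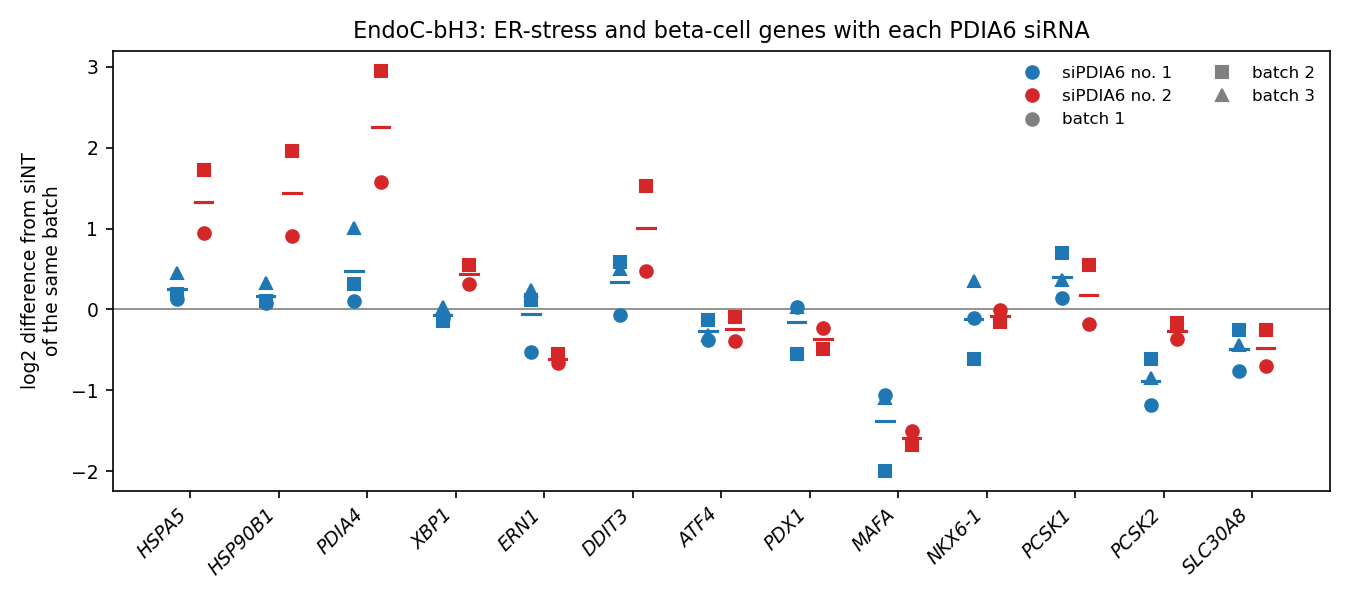
Log2 difference of each PDIA6 siRNA library from the siNT library of the same batch for 13 ER stress and β-cell genes fixed in advance in EndoC-bH3. Points are libraries (blue, siRNA 1, n = 3; red, siRNA 2, n = 2) and dashes are means; both siRNA 2 libraries lie above the siRNA 1 libraries of their batch for HSPA5, HSP90B1 and PDIA4, and MAFA lies between −1.99 and −1.06 in all 5 libraries.

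For siRNA 1 against siNT, limma called 134 genes (77 rose and 57 fell), and with batch as a block 5105 (2718 rose and 2387 fell). Named after the blocked values were seen, CYP1A1, a target gene of the aryl hydrocarbon receptor, rose from 26.65 ± 2.11 to 375.6 ± 229 (SD, n = 3 each), a log2 difference of 3.55 that passed with the block (limma adjusted p = 9.56e-05) and without (0.0315). The transporter genes ABCC2 and ABCA10 rose by 3.34 and 3.12. MDK, which encodes the growth factor midkine, fell by 3.04 (limma adjusted p = 0.00829 without and 8.22e-06 with the block), and MDGA1 also fell (−2.63). With limma, LHFPL3-AS2 and CLEC7A rose, and CABP4 (−2.75) and PPP1R17 (−2.51) fell, with the block and not without it, and DESeq2 without a block also called CABP4 (adjusted p = 0.00619). LHFPL3-AS2 stood at 0 to 29.0 with siNT and 15.6 to 294 with siRNA 1, and CLEC7A at 0 to 6.24 and 2.08 to 505, so a fold over these controls depends on the pseudocount. LHFPL3-AS2 is antisense to a coding gene, and the strand setting of the counting is not given in the sources used here. The unblocked count was 26, 0 and 5 without siNT of batch 1, 2 or 3, 27, 0 and 2 without siRNA 1 of batch 1, 2 or 3, and 83 and 75 without siRNA 2 of batch 1 or 2. The blocked count was 2978 without siNT of batch 3 and 3324 and 2990 without siRNA 1 of batch 2 or 3. For siRNA 2 against siNT, limma called 1 gene, PDIA6 (adjusted p = 0.0145; 859 genes at an unadjusted p under 0.05), and with the block 1622 (659 rose and 963 fell; 859 and 763 after centring each library on its median). Named after the blocked values were seen, DERL3, a gene of ER-associated degradation, rose by 2.73, IL23R by 2.10, PIK3R5 by 1.94 and NETO1 by 1.93, with PDIA4 second among the largest rises. ECEL1, an endopeptidase-like gene, fell by 2.69, LCN10 by 2.35 and the potassium channel gene KCNQ1 by 2.22. STYK1 also fell with limma and the block (adjusted p = 0.0338), but edgeR with the block did not call it (−1.32, adjusted p = 0.081). It stood at 104 and 0 with siRNA 2, so its fold depends on the pseudocount, with an unblocked log2 difference of −2.68 at 0.5 and −1.19 at 5. The PDIA6 call was lost without any 1 of the siNT libraries, siRNA 1 of batch 2 or 3 or siRNA 2 of batch 1, where the count was 0. The blocked count was 963 and 880 without siNT of batch 2 or 3, 888 without siRNA 1 of batch 3, and 480 and 721 without siRNA 2 of batch 1 or 2, where the lone siRNA 2 library is assumed to vary like the other groups. Without siRNA 2 of batch 2, the unblocked log2 difference of STYK1 was 1.16, against −2.20 with all libraries.

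Gene lists, tested for each siRNA with batch as a block, gave 5 calls for siRNA 1 and 9 for siRNA 2, against 3 and 2 without the block. Over all 16196 genes, 2718 rose and 2387 fell with siRNA 1, and 659 rose and 963 fell with siRNA 2. Counts of called members are to be read against these shares, which some of them barely exceed, such as 2 of 28 in the heat shock list with siRNA 2. The 5 for siRNA 1 rest on the preset correlation, and each had adjusted p = 0.867 with an estimated one. With siRNA 1, β-cell identity genes fell as a group (12 of 28 members fell; camera adjusted p = 4.36e-05; 0.867 estimated), including UCN3, MAFA, RFX6 and G6PC2. Ribosomal protein genes (23 of 47 rose and 1 fell; 4.92e-07; 0.867 estimated) and oxidative phosphorylation genes (10 of 42 rose; 0.000437; 0.867 estimated) rose as groups. Glycolysis and hypoxia genes (12 of 26 rose and 2 fell; 0.0141; 0.867 estimated), such as PGAM1, ENO2, LDHA and NDRG1, rose as a group, and SLC2A1 was among those that fell. The heat shock and oxidative stress list was also higher (12 of 28 rose and 4 fell; 0.027; 0.867 estimated), with NQO1, GCLC, SRXN1, TXNRD1 and SLC7A11, genes that NRF2 is known to induce, among those that rose. With siRNA 2, cholesterol synthesis genes fell as a group (16 of 25 fell; camera adjusted p = 4.16e-13; adjusted p = 0.651 with an estimated correlation), with TM7SF2 at −1.16, MVD at −0.96 and MSMO1 at −0.81. ER chaperone genes rose as a group (10 of 26 rose and 1 fell; 0.00013; adjusted p = 0.651 with an estimated correlation), with CRELD1, HSP90B1, HSPA5, MANF (1.38), HYOU1 (1.28) and DNAJC3 (1.24) among them. ER-associated degradation genes rose as a group (8 of 27 rose and 1 fell; 0.0188; adjusted p = 0.729 with an estimated correlation), with SEL1L at 1.27 and HERPUD1 at 0.74. Ribosomal protein genes were higher as a group (3 of 47 rose and 1 fell; 8.6e-05; adjusted p = 0.884 with an estimated correlation), as was the interferon list (3 of 22 rose; 0.0386; adjusted p = 0.651 with an estimated correlation). The lists for β-cell identity (5 of 28 fell and 1 rose; 0.00493; adjusted p = 0.651 with an estimated correlation), PERK-ATF4 (5 of 35 fell and 2 rose; 0.00711; adjusted p = 0.651), heat shock and oxidative stress (2 of 28 fell and 1 rose; 0.0386; adjusted p = 0.884) and prohormone processing (3 of 23 fell; 0.0483; adjusted p = 0.729) were lower, where the second p is again with an estimated correlation.

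**Figure D3:**
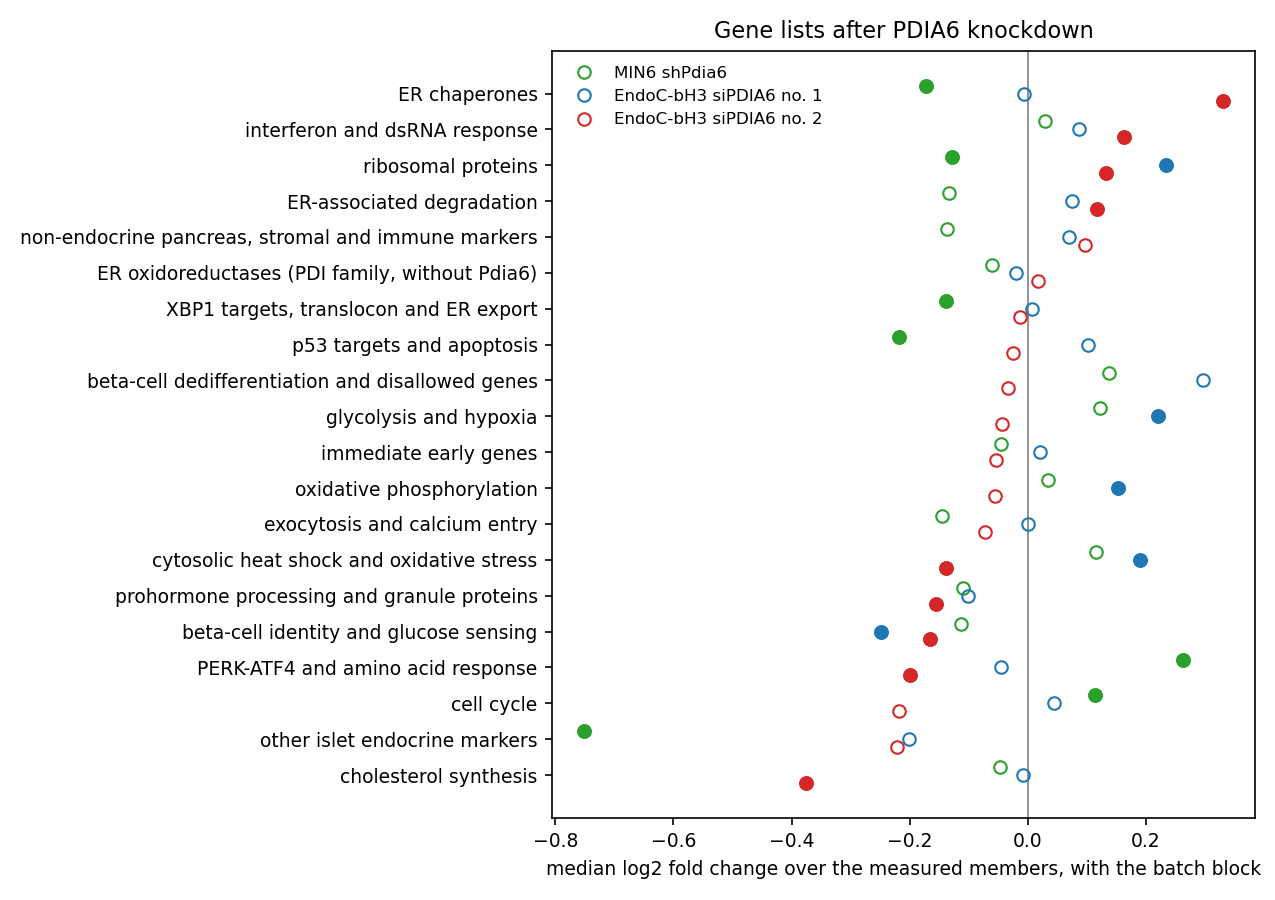
Median log2 difference from control of the members of each of the 20 fixed gene lists, with batch as a block, in MIN6 (green), EndoC-bH3 with siRNA 1 (blue) and EndoC-bH3 with siRNA 2 (red). Filled points have a camera adjusted p under 0.05 with the preset correlation; the siRNA 2 point for cholesterol synthesis is at −0.38 and that for ER chaperones at 0.33, against −0.0074 and −0.0065 for siRNA 1.

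The siRNAs were also compared directly, which tests the difference between their effects. Without a block limma called 5 genes. CHRNA3, a nicotinic acetylcholine receptor subunit gene, stood at 4196 ± 687 (SD, n = 3) with siRNA 1 and 980.3 ± 107 (SD, n = 2) with siRNA 2, where siNT was at 834.6 ± 44.8 (SD, n = 3), a log2 difference of 2.09 ± 0.16 (SE) between the siRNAs. The kinase gene PAK1 differed by 1.32 and the vesicle trafficking GTPase gene RAB8A by −1.26. The other calls, named after their values were seen, were the dynein light chain gene DYNLRB1 (−1.91) and TFDP1 (−1.48), which encodes the dimerisation partner of E2F. All 5 had a limma adjusted p of 0.0499, and TFDP1, DYNLRB1, PAK1, RAB8A and CHRNA3 passed with siRNA 1 against siNT and not with siRNA 2. Leaving out siRNA 1 of batch 1 left 1 call, and leaving out any other library left 0. With batch as a block 3797 genes passed, 2211 higher and 1586 lower with siRNA 1, and the 5 genes were among them. Named after these values were seen, LHFPL3-AS2, ABCC2 (2.64), CLIC5 (2.52) and the NRF2 target gene NQO1 (1.99) were higher with siRNA 1, besides CYP1A1 (3.67) and ABCA10 (2.86). DERL3 (−2.23), PIK3R5, KCNMB2 (−1.90), RTN4RL1 (−1.75), MDK (−1.68) and CHIC2 (−1.63) were lower with siRNA 1. Leaving out siRNA 1 of batch 2 gave 1968 calls, and leaving out siRNA 2 of batch 1 or 2 gave 1702 and 1493, again with the spread taken from the other groups. With the block 7 lists passed with the preset correlation, each with adjusted p = 0.8 with an estimated one, and 6 passed without the block. Of these 7, cholesterol synthesis (17 of 25 members higher with siRNA 1; camera adjusted p = 1.14e-07), oxidative phosphorylation (15 of 42; 3.4e-06), heat shock and oxidative stress (13 of 28, with 1 lower; 0.000334), glycolysis (8 of 26, with 2 lower; 0.0115), p53 targets (8 of 25, with 1 lower; 0.0352) and cell cycle (6 of 40; 0.043) were higher with siRNA 1. ER chaperones were lower with siRNA 1 (12 of 26; 1.78e-05; 0.8 estimated). Over all 16196 genes, 2211 were higher and 1586 lower with siRNA 1, and the cell cycle count (6 of 40) is near that share.

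Genes called with each siRNA against siNT were then compared. With batch as a block 850 genes passed in the same direction with both siRNAs (400 up and 450 down), and 93 in opposite directions. Lists drawn independently would share 111 up and 142 down, and simulated unchanged groups against the same siNT libraries shared 0 on average over 100 simulations. Groups simulated without changes yield few calls at this threshold, so that 0 does not gauge the part played by shared controls. Both comparisons use the same 3 control libraries, which were not divided between the siRNAs, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, the fold changes correlated with r = 0.441, against 0.428 in the simulated groups. Their covariance was 0.0851 against a simulated 0.0178, a difference of 0.0673. Without the block 1 gene, PDIA6, was shared, r was 0.445 against a simulated 0.446, and the covariance of 0.0872 was below the simulated 0.0999 by −0.0127.

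Fold changes in MIN6 and EndoC-bH3 were set side by side for 10660 genes matched by symbol. Across these genes, which are not independent replicates, Pearson's r was 0.037, and 0.029 without PDIA6. It lay between 0.0148, without the shPdia6 library of batch 1, and 0.0523, without that of batch 2, whichever library was left out, and was 0.0226 without siRNA 1 of batch 1. No gene passed in both lines, since limma called 0 in MIN6. Of the 10 EndoC-bH3 calls with a MIN6 counterpart, 6 had the same sign in MIN6, and with batch as a block 155 of 298. Ribosomal protein genes were lower as a group in MIN6 and higher in EndoC-bH3 with the preset correlation (adjusted p = 0.76 and 0.922 with an estimated one), and whether these differences differ between the lines was not tested.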

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

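The searches for 7-base matches, the comparison of PDIA6 levels, the tests of abundant transcripts and the counts of other splits were chosen only after the results were seen, while the tests of direct matches as the whole difference and of GC content and length were set beforehand.

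The siRNAs against PDIA6 differed in a direct test of their difference, which called 5 genes without a block, among them CHRNA3 (2.09 log2), PAK1 (1.32) and RAB8A (−1.26). Unequal knockdown was argued against by the PDIA6 difference of −0.07501 (SE 0.18), and a trend on GC content or transcript length as the whole cause by the 88.59% of the calls with batch as a block that were kept after both trends were removed. Short matches between each siRNA and other transcripts (seed matches) may contribute, though the siRNA and hairpin sequences were not available to compare: carriers of 1 7-base word in the 3′ UTR were lower with siRNA 1 (z = −12.29) and of another with siRNA 2 (z = −12.08), and RAB8A, CHIC2 and PCSK2, which fell with siRNA 1, carry the first word, as do ABCC2 and DSC2, which rose. The words overlap, and carriers of a word overlapping both were lower with each siRNA (z = −6.334 and −10.956), but between the siRNAs carriers of the first were lower with siRNA 1 (z = −11.884) and of the second with siRNA 2 (z = 8.208); their presence in PDIA6 outside its 3′ UTR, or of the leading word of 3 of 3 MIN6 hairpins in Pdia6, is shared by 20.47% and 19.38% of all words. Direct matches to the strongest words in the searched 3′ UTRs were not the whole difference. With the block, 25.67% of the 8131 genes without those words were called between the siRNAs, against 33.91% of 3845 carriers. Genes with weaker words or with matches outside the 3′ UTR stayed among the 8131, so direct matches of every kind were not excluded. Secondary effects, and effects of PDIA6 loss that differ between siRNAs, were not tested.

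Changes shared by both siRNAs can also come from the control they share. Among the 203 genes with a searched 3′ UTR that rose in the pooled comparison with batch as a block, 66 (32.51%) carried 1 7-base word, against 8.4% of length-matched genes, a ratio of 3.869. The word was picked because its carriers rose most in these libraries, so the ratio partly restates that choice. As the leading word of batch 1 alone (z = 10.7) it also led in batches 2 and 3 (z = 7.86 and 7.08). In the pooled comparison carriers of an unrelated word rose nearly as strongly (z = 8.944 against 9.282), so the rise is not particular to the leading word. A seed match of the non-targeting siRNA, relieved in the knockdown libraries, is a candidate explanation for part of the rise. The sequence of that siRNA was not available to check it. CBX1, TMEM209, RAP1B and DSC2 carry the leading word, while RSL24D1, PGAM1, SGCE and GNPNAT1, which also rose, do not. PSAT1, CYP2C19, ADH6, PROS1 and METTL7B, which rose with the block, do not carry it either. The 3′ UTRs of RAP1B and DSC2 are long (12652 and 9383 bases, against a median of 1604), so any word is more likely in them. Direct relief of a match can only raise transcripts, so it does not account directly for the 46.33% of the pooled calls with batch as a block that fell, MAFA among them, while falls downstream of relieved genes were not tested and loss of PDIA6 remains open for both directions. In MIN6, carriers of 1 word also rose in the mean of the hairpins against shNT (z = 9.747, highest of shuffled genes 5.36). Their median was 0.0221 (log2) against −0.0116 for other genes. For the hairpins of batches 1, 2 and 3 the z was 6.176, 6.233 and 8.783. All were set against the same shNT libraries, so a match of the non-targeting hairpin is likewise a candidate there and was not tested.

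Abundant transcripts were high in the shPdia6 library of batch 2, the shallowest in MIN6. There the 100 most abundant genes had a median of 0.383 (log2) over shNT of batches 1 and 2, the reference for all medians here. Iapp, the amyloid polypeptide gene of β-cells, stood at 156400 there and at 64820 to 83060 with shNT. Whether the Pdia6 hairpins share an effect could not be decided from the other shPdia6 libraries, where the same genes had medians of −0.189 and −0.186. Those libraries were the deepest in MIN6 (24755916 and 22556147 reads), so depth could hide a common rise. The median fell as depth rose across all MIN6 libraries. Between these extremes it was 0.163 in shNT of batch 3, 0.0143 in shNT of batch 2 and −0.0143 in shNT of batch 1. Removal of duplicates, which limits abundant transcripts more in deeper libraries, may contribute: the shNT library of batch 3 (9116880 reads) had a median of 0.163 over the deeper shNT libraries, a value between the bounds set for and against it, so the cause is undecided. An effect of the hairpin of batch 2 alone cannot be told apart from batch and depth.

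Other divisions of the libraries into groups of the same sizes were counted. For the 14 genes called in EndoC-bH3, 3 of 56 splits gave as many, so chance was not excluded. The highest other, 7393 genes, set the batch 1 libraries against the rest, which points to the batch structure for that split. Of the 18 splits with 1 control library from each batch, 2 gave as many, the real one included. The highest other of these gave 141 genes, so large splits did not come from batch alone. With batch as a block 2 of 18 splits gave at least the 395 genes, and the split with the siRNA 1 libraries as controls gave 2971; the splits are too few for a share under 0.05. For the 3 EndoC-bH3 lists, 52 of 56 splits gave as many (highest other 10), as did 16 of the 18 with 1 control library from each batch, so chance was not excluded; no list split was run with batch as a block. For siRNA 1 against siNT the real split gave 134 genes and the highest other 0 (1 of 10 splits), and with the block 5105 and 0 (1 of 4), again too few. In MIN6, limma called 0 genes (1279 at an unadjusted p under 0.05, edgeR 0 and DESeq2 91). There 10 of 10 splits gave as many (highest other 0), which a real count of 0 makes certain. For the 6 MIN6 lists, 6 of 10 splits gave as many, with a highest other of 9, so chance was not excluded. These splits are also too few for a share under 0.05.

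Of 62 genes compared between the lines, 10 lay on opposite sides of control in every library of each line, and whether the lines differ was not tested. Genes on the same side in every library were not counted. Some of the 62 were named because the libraries of 1 line all moved the same way. The log2 differences in MIN6 and EndoC-bH3 were 0.83 and −0.18 for Ilrun, −0.39 and 0.93 for Rap1b, −0.79 and 0.72 for Dsc2, 0.89 and −1.26 for Glipr2, 0.14 and −0.28 for Atf4, and −0.33 and 0.11 for Srp19. They were 0.30 and −1.71 for G6pc2, −0.44 and 0.21 for Rps7, −0.35 and 0.21 for Rpl7, and −0.33 and 0.27 for Rps19. Among 38 named EndoC-bH3 genes, none had a single PDIA6 siRNA library far from the other PDIA6 siRNA libraries. Neither the siNT libraries nor MIN6 were covered by that check.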

How the results depend on the processing

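The blocked comparisons with a library left out, rescaled or refiltered, and the averaging of shNT libraries 1 and 2 in MIN6, were chosen only after the results were seen. Across 121 results for named genes (target and insulin genes not counted), alternatives kept direction and side of the threshold in 2075 cases. They crossed to called in 142, lost the call in 168 and turned direction in 32. Only the 20 called results could lose a call, so all 168 losses fell on them. Losses per called result ranged from 4 (such as CBX1, of 21 alternatives) to 13 (PAK1 between the siRNAs, of 20). Of the 20 called results 0 turned direction, and 10 uncalled ones did. The adjusted p of CBX1 ranged from 1.55e-30 to 0.0831 and that of RSL24D1 from 2.5e-11 to 0.285 over 21 alternatives. Where a count moved, the cause was not tested. Robust moderation was not run for lists. Where 1 siRNA 2 library is left, it is assumed to vary like the other groups. In simulated MIN6 data, which kept batch effects shared by the same batch number, limma recovered 14% of 2-fold and 75% of 4-fold changes. The MIN6 libraries showed little such pairing, so these shares may not hold for them. What the depth of the shallowest library, 1987770 reads, limits at each count level was not tested.

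Counts of called genes moved as follows. In MIN6 (0 by limma, 1279 at an unadjusted p under 0.05, edgeR 0) array weights gave 222 and DESeq2 91. In pooled EndoC-bH3 (14) no filter gave 9, the block 395, array weights 1105, DESeq2 289, edgeR with the block 437, equal weighting of the siRNAs 36, and leaving out a library 1 to 4. For siRNA 1 (134) the block gave 5105, array weights 2951, DESeq2 1043, edgeR with the block 5190, and leaving out a library 0 to 83. For siRNA 2 (1) the block gave 1622, DESeq2 254, edgeR with the block 1647, and leaving out a library 0 to 1. Between the siRNAs (5) a pseudocount of 0.5, no filter and robust moderation each gave 0, median centring 3, the block 3797, DESeq2 665, edgeR with the block 3866, and leaving out a library 0 to 1. With the block, leaving out a library gave 2 to 833 pooled, 2978 to 4860 for siRNA 1, 480 to 2084 for siRNA 2 and 1493 to 4058 between them. The siRNAs shared 850 calls with the block.

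Of the lists, array weights gave 12 in MIN6, the estimated correlation and fry 0 each, and leaving out a library 2 to 9; in EndoC-bH3 the estimated correlation and fry without the block gave 0 each (fry with the block gave 2), and leaving out a library 1 to 6. The correlation between lines lay between 0.0148 and 0.0523 with a library left out. Ins1 lay between −0.45 and 0.49, Ins2 between −0.55 and 0.34 (−0.0028 with TMM) and INS between −0.47 and 0.013.

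Besides the insulin genes, these uncalled genes turned direction. Hspa5 was 0.021 with edgeR, 0.030 with DESeq2 and −0.19 to 0.11 with a library left out; Hsp90b1 was 0.0041, 0.013 and −0.19 to 0.10. Pcsk2 was 0.00023 with median centring, 0.026 with array weights, 0.020 with edgeR, 0.030 with DESeq2 and −0.16 to 0.15 with a library left out. With a library left out, Pdia4 was −0.40 to 0.098, Xbp1 −0.23 to 0.025, Mafa −0.21 to 0.39, PDX1 −0.39 to 0.056 and STYK1 with siRNA 2 −5.56 to 1.16. ERN1 was 0.071 with array weights and −0.42 to 0.0054 with a library left out. NKX6-1 was −0.065 with the block, −0.0068 with edgeR, −0.00089 with DESeq2, −0.069 with edgeR and the block, and −0.33 to 0.29 with a library left out.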

Other observations

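Targets of p53 differed among themselves in EndoC-bH3. With siRNA 1 and batch as a block, ZMAT3 rose by 1.31 (log2), GDF15, a secreted stress cytokine gene, by 1.31 and the cell cycle inhibitor gene CDKN1A by 0.90, while the list of p53 targets had a camera adjusted p of 0.199 (8 of 25 rose and 3 fell). With siRNA 2, ZMAT3 rose by 1.05, and GDF15 and CDKN1A differed by 0.25 and −0.10. Without the block, GDF15 passed with siRNA 1 (limma adjusted p = 0.0466), and ZMAT3 and CDKN1A passed with neither siRNA. These genes, and those in the next paragraph apart from DDIT3, were chosen after their values were seen.

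Genes that mature β-cells keep low also went separate ways with siRNA 1 and the block. NEUROG3, a gene of endocrine progenitors, fell by 1.91 and the repressor gene REST by 1.38, while LDHA differed by 0.56, a rise that passed. The list of dedifferentiation and disallowed genes had a camera adjusted p of 0.532. Of interferon genes, with the block, IRF7 rose by 0.81 with siRNA 1 and 0.96 with siRNA 2, and IFIH1, a sensor of double-stranded RNA, by 1.16 and 1.07. The interferon list as a group did not pass with siRNA 1 and the block. In the amino acid response list, which was lower as a group with siRNA 2 and the block (adjusted p = 0.651 with an estimated correlation), PSAT1 (1.30) and DDIT3 (1.04) rose and TRIB3 (−0.41) was among the genes that fell. Without the block, limma called none of these genes in the same comparisons.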
